A study of Mus musculus with 8 samples.

How the data were processed

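RNA was taken from fluorescence-sorted tdTomato-positive cells of the somatosensory cortex in 8 samples, 4 WT and 4 Ptch1cKO. Per the labels' protocols, cDNA was made with a low-input amplification system and enriched with Illumina TruSeq RNA exome capture reagents, which pull down coding sequence with probes. Levels of different genes therefore depend on capture as well as on abundance, and are compared here between libraries. Reads were demultiplexed with bcl2fastq 2.18 and STAR 2.5 was used, with the genome build mm10, per the submitters' processing notes. The program that counted reads, the annotation and the strand setting are not given in the sources used here.

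The deposited counts are whole numbers of reads per gene symbol, not normalized, in 24047 rows with 24045 symbols. In 27 rows the symbol had become a date, and those rows were tested under the name given. A second deposited table holds TPM, computed by the authors, in 23585 rows. For 5673 genes the ratio of count to TPM, after 1 factor per library, differed between libraries by at most 1.01-fold, so both tables hold the same counts. The 462 rows found only among the counts held at most 133 reads in any library. No row held a gene of the mitochondrial genome, so the planned mitochondrial share and the list of those genes were not computed. The ribosomal precursor row Rn45s held 1.87 to 2.94% of the counts of a library. Gene positions come from GENCODE M21 on GRCm38, the same assembly as mm10, in which 23519 symbols matched 1 gene.

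Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group (default minimum count 10), which kept 10954 of 20578 genes with a count, and libraries were scaled with TMM factors. The quasi-likelihood F test (glmQLFit with robust estimation) compared Ptch1cKO with WT in all 8 libraries with the group as the only term, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. CPM values use the TMM-scaled library sizes, and the SE of a log2 fold change was taken as its size divided by the square root of F. The median log2 fold change of all genes was -0.0019. The biological coefficient of variation was 0.253. An unadjusted p under 0.05 was found for 1023 genes, where 548 are expected by chance. The groups did not overlap in 550 genes, 5.02% of those tested, where chance gives 2.86%. Both chance values are averages, and genes that vary together can move a count far from them. Parting WT replicates 1 and 2 and Ptch1cKO replicates 1 and 3 from the rest gave 1111 genes with an unadjusted p under 0.05 by the same edgeR test. The 1023 genes alone therefore do not show a difference by genotype.

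Before the data were examined, 41 gene lists were written from knowledge of the tissue and pathway, 1 of them recalled from the published study of these mice. The 34 lists with at least 5 tested members were compared with camera in limma 3.58.1 on voom-weighted log2 CPM with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. Library-level values were compared with an exact two-sided permutation test over 70 assignments. Replicate numbers in the titles were not used as pairs. Libraries were checked for duplicates with a chi-square test of counts, and none agreed within sampling noise. The sample numbers of the mutants in the descriptions are 1, 2, 4 and 5, and titles number them 1 to 4, which is the numbering used here. Column names carry prefixes that group libraries within a genotype, and what they stand for is not given in the sources used here.

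The rule for named genes was fixed before the data were examined. It took Ptch1 and every measured Hedgehog target, then Lrig1, Sparc, Sparcl1 and Kcnj10. It took the 12 strongest rises and 12 strongest falls among called genes with a mean of at least 1 CPM and no overlap between groups, leaving out symbols that do not start with letters, and up to 4 called members of each list. For a list that passed camera without a called member, it took the 3 members with the smallest p, as values only. The row 4-Sep, Smo, Aldh1l1, Nkx2-9, Ephb1, Csf1r and the sex-linked genes fall outside the rule and were chosen after their values were seen. A few items that the rule takes are not reported here.

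The test was checked on simulated data made from the means and library sizes of these samples, with 200 genes changed. With 10955 genes tested, it recovered 14% of genes changed 1.5-fold, 38% of those changed 2-fold, 76% of those changed 3-fold and 90% of those changed 4-fold, and 9 of 118 calls were false. Without the count filter, 26 of 143 calls were false. A simulated list raised 1.5-fold was called and 0 of 33 unchanged lists were. Genes were simulated independently, whereas the lists that passed camera in the data had estimated inter-gene correlations of 0.20 to 0.64. The simulation therefore does not show how often correlated lists are called falsely. Genes without about 10 counts in at least 4 libraries could not be tested, and intervals on pooled counts cover counting error only. A gene with few counts in a group could still be tested, as Mei1 was through its WT libraries.

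Alternatives fixed before the data were examined were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with and without sample weights, other count filters, limma on log2 TPM with pseudocounts of 1 and 0.1, each library left out, the replicate number as a block, Xist as a covariate, 1 surrogate variable from sva 3.50.0, a cell type covariate and a fold change of at least 1.5. Added after seeing the data were the 6 libraries with under 10 Xist counts, astrocyte or microglial marker levels as covariates, and the counts without Rn45s.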

Results

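RNA was sequenced from cells sorted as astrocytes from the mouse somatosensory cortex, the region that receives touch input. The mice carried a tamoxifen-inducible Cre recombinase under the Glast promoter together with the Ai14 reporter, so that cells in which Cre had acted, and their progeny, turned on the red fluorescent protein tdTomato. Tamoxifen was given on postnatal days 12 to 14, and tdTomato-positive cells were sorted from animals aged 23 to 25 days. The 4 control libraries (WT) came from mice with normal Ptch1, and the 4 mutant libraries (Ptch1cKO) from mice in which both copies of Ptch1 were floxed. Ptch1 encodes the Sonic hedgehog receptor, which holds the transducer Smo inactive when no ligand is bound, so its removal is used to switch the pathway on. The comparison asks which transcripts differ in cortical astrocytes when this brake is removed during postnatal development. Total counts were 5759680, 6210965, 7206462 and 4958119 in WT replicates 1 to 4, and 7043378, 6070713, 4061274 and 6061480 in Ptch1cKO replicates 1 to 4. Between 15175 and 17554 genes had at least 1 count in a library. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these samples.

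Ptch1, the targeted gene, had a mean of 223 ± 40.8 CPM (library-size-scaled counts, SD, n = 4) in Ptch1cKO and 357 ± 122 CPM (SD, n = 4) in WT. The fold change was -0.67 on the log2 scale with a standard error (SE) of 0.22. For this gene, named in advance, the unadjusted p was 0.00765, and it did not pass the test over all genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.349). The ranges of both groups overlapped. Ptch1 lies on chromosome 13 of mm10 at 63508328 to 63573598, minus strand, and the count covers the whole gene, so a transcript that lacks single exons is still counted. In the authors' deposited TPM, which also scale for transcript length, the means were 133 ± 28.8 in Ptch1cKO and 230 ± 80.5 in WT (SD, n = 4).

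The transcript with the smallest p-value was Sparc, a secreted matricellular protein made by astrocytes that limits synapse formation and maturation. It rose 2.82-fold, from 1221 ± 202 CPM in WT to 3436 ± 614 CPM in Ptch1cKO (SD, n = 4). The AMPA-type glutamate receptor subunit Gria1 rose 2.94-fold and Aldh1a1, an enzyme that makes retinoic acid, rose 2.61-fold. Kcnip3, a calcium-binding protein that acts on potassium channels and transcription, rose 2.16-fold. In all, 11 of 10954 genes tested passed, of which 9 were higher and 2 lower in Ptch1cKO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05).

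Each of the 11 genes had its 4 libraries of one group all above the 4 of the other. For Sparc (chromosome 11, 55394500 to 55423183, minus strand) the log2 fold change was 1.49 (SE 0.15). The values were 1.56 (SE 0.23) for Gria1 (chromosome 11, 57011387 to 57330244, plus strand) and 1.11 (SE 0.16) for Kcnip3 (chromosome 2, 127456498 to 127522094, minus strand). Aldh1a1 (chromosome 19, 20492715 to 20643465, plus strand) changed by 1.39 (SE 0.22), from 139 ± 38.9 to 363 ± 104 CPM (SD, n = 4). Gria1 went from 244 ± 53.6 to 718 ± 240 CPM and Kcnip3 from 159 ± 18.5 to 343 ± 71.6 CPM (SD, n = 4). Smaller rises were found for Abhd4, a lipid hydrolase of N-acylethanolamine metabolism (chromosome 14, 54254188 to 54270637, plus strand), at 0.78 (SE 0.13), and for the tetraspanin Cd81 (chromosome 7, 143052739 to 143067934, plus strand), at 0.70 (SE 0.12). An exon of Cd81 overlaps the opposite-strand gene R74862, and an exon of Tmem255a overlaps opposite-strand Zbtb33. Whether the counting used strand is not given in the sources used here, so reads of these partners cannot be told apart. Tmem255a, a membrane protein gene on the X chromosome (38196573 to 38252439, minus strand), rose 2.37-fold, at 1.25 (SE 0.22). A further gene that rose is listed as 4-Sep, a symbol damaged into a date, at 1.16 (SE 0.19), and no gene name is assigned to it here. By edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p was 0.000476 for Sparc, 0.0155 for Kcnip3, 0.0286 for Gria1, 0.0356 for Abhd4, 0.0371 for Aldh1a1, 0.0371 for the row 4-Sep, 0.0428 for Tmem255a and 0.0466 for Cd81.

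The genes that fell were Tmem28 and Mei1. Tmem28, a membrane protein gene on the X chromosome (99821021 to 99848790, plus strand), fell from 22.8 ± 3.09 to 8.83 ± 1.96 CPM (SD, n = 4), a log2 fold change of -1.37 (SE 0.24; edgeR, Benjamini-Hochberg adjusted p = 0.0428). Mei1, known for its part in meiotic recombination (chromosome 15, 82069996 to 82126814, plus strand), fell from 3.30 ± 0.656 to 0.316 ± 0.219 CPM (SD, n = 4), with a log2 fold change of -3.35 (SE 0.59; edgeR, Benjamini-Hochberg adjusted p = 0.0464). Mei1 counts were 20, 19, 30 and 13 in the WT libraries and 3, 2, 2 and 0 in the Ptch1cKO libraries.

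**Figure D1:**
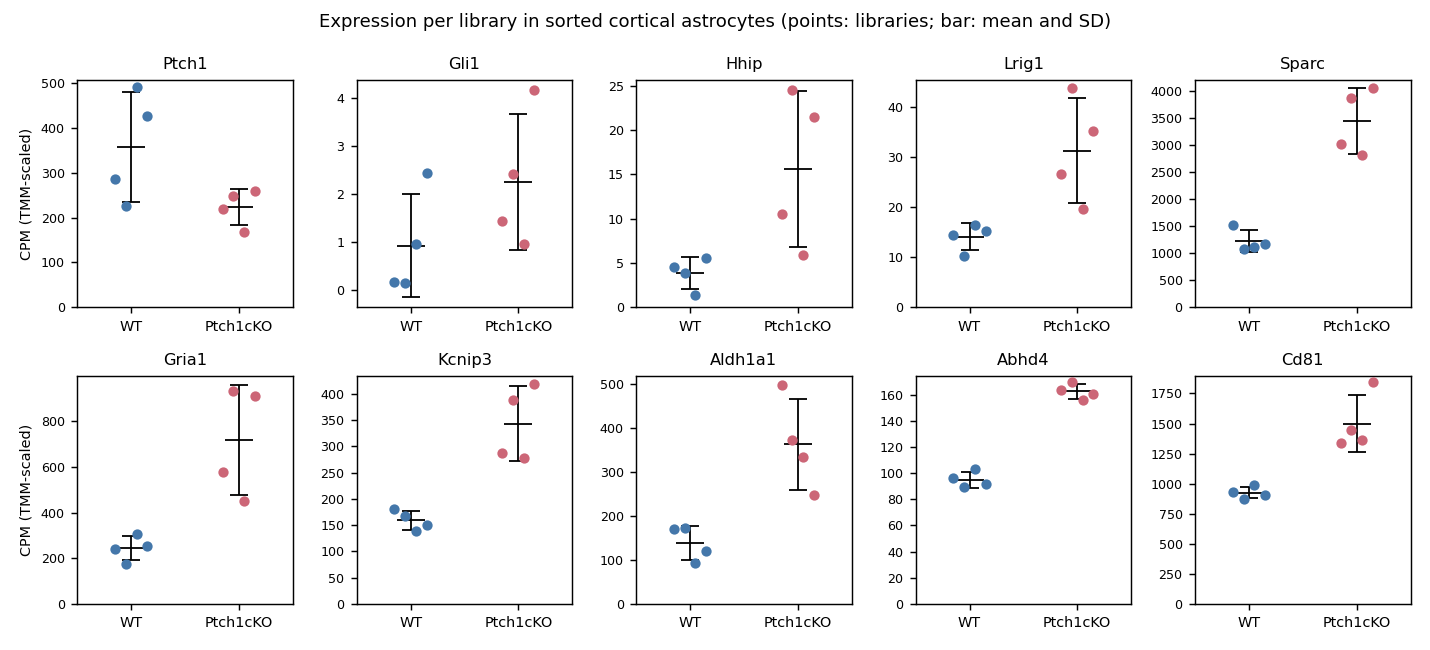
TMM-scaled CPM (vertical axes from 0, or just below it for Gli1, where the SD bar crosses 0) of 10 genes in the 4 WT and 4 Ptch1cKO libraries; points are libraries, and bars are the mean and SD. Sparc, Gria1, Kcnip3, Aldh1a1, Abhd4 and Cd81 passed the test over all genes, whereas Ptch1, Gli1, Hhip and Lrig1 did not, and the Ptch1 and Gli1 values of the groups overlap.

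The libraries also differed in sex-linked transcripts. Xist, expressed from the inactive X of females, had 1148 and 612 counts in WT replicates 2 and 3 and at most 4 counts in each of the other 6 libraries. The Y-linked gene Ddx3y had 0 counts in those 2 WT libraries and 498 to 1073 in the others, so the 4 Ptch1cKO libraries were all of the male pattern and the WT group was mixed. Among the 6 libraries with under 10 Xist counts, 3 genes passed (1 higher, 2 lower), of which only Sparc was among the 11 (log2 fold change 1.35, SE 0.20; edgeR, Benjamini-Hochberg adjusted p = 0.0435). There, X-linked Tmem28 had a log2 fold change of -1.24 (SE 0.30) and Tmem255a one of 1.33 (SE 0.29), and neither passed. Leaving out single libraries left between 1 and 19 genes, with Sparc among them each time.

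Hedgehog target genes were next examined, as genes that Gli transcription factors switch on. Of 18 listed targets, 9 had enough counts to be tested, none rose or fell over all genes, and 5 of the 9 had positive and 4 negative fold changes. The targeted gene Ptch1 is among these 9, so its own fall enters these counts and the set test below. The set was not tested without it. Adjusted over the list alone, 3 were higher and 2 lower. The Hedgehog-binding inhibitor Hhip, a classical target, had 3.86 ± 1.77 CPM in WT and 15.6 ± 8.83 CPM in Ptch1cKO (SD, n = 4), with all 4 Ptch1cKO libraries above the 4 WT libraries. Its log2 fold change was 2.04 (SE 0.46; edgeR, Benjamini-Hochberg adjusted p = 0.146 over all genes and 0.00504 over the list). DESeq2, which called 83 genes in all, called Hhip (Benjamini-Hochberg adjusted p = 0.00539). In the 6 libraries with under 10 Xist counts, which are fewer samples, Hhip had a log2 fold change of 1.64 (SE 0.53) and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.478). Sfrp1, a secreted Wnt antagonist, had a log2 fold change of 0.88 (SE 0.34) and the cyclin Ccnd1 0.32 (SE 0.13), whereas Ccnd2 had -0.86 (SE 0.23) and Ptch1 itself, as above, was the other gene that was lower over the list. Exons of Ccnd1, Ccnd2, Nkx2-2 and Bcl2 overlap genes on the opposite strand. The fold changes of Rab34, Mtss1, Nkx2-2 and Bcl2 were 0.54 (SE 0.30), -0.46 (SE 0.26), 0.26 (SE 0.37) and -0.15 (SE 0.16). As a set, the targets did not pass (limma camera, Benjamini-Hochberg adjusted p = 0.668; p = 0.611 with an estimated correlation). Without the filter on low counts, which brings in the targets with few counts, the set passed as higher in Ptch1cKO (camera with the preset correlation, Benjamini-Hochberg adjusted p = 0.0443), and adjusted p-values were 0.143 to 0.959 in the other alternatives, with the direction turned in the 6 libraries with under 10 Xist counts. Of 14 tested ligands, receptors and transducers of the pathway, 0 passed by edgeR over all genes, 7 had positive and 7 negative fold changes, and 1 had an unadjusted p under 0.05. That gene was Smo, at 0.68 (SE 0.24).

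Another 8 targets lay below the count filter, and Nkx2-9 had no count. Gli1, the transcription factor most often used as a readout of the pathway, had 1, 1, 7 and 12 counts in WT and 10, 14, 4 and 25 in Ptch1cKO. Pooled over the 4 libraries of a group the ratio was 2.62 (95% exact interval 1.55 to 4.58, covering counting error only), and the difference between libraries did not pass (exact two-sided permutation test, p = 0.2, adjusted p = 0.533 by Benjamini-Hochberg over these 8 genes). The smallest p that this exact test can give is 0.0286, and a single gene at that p would not pass over 8 genes. The failure to pass is therefore weak evidence that Gli1 was unchanged. By edgeR without the count filter, Gli1 had a log2 fold change of 1.32 (SE 0.64, unadjusted p = 0.040). Its Benjamini-Hochberg adjusted p was 0.480 over all genes and 0.097 over the 17 targets with a count. Mycn had 31 pooled counts in WT and 33 in Ptch1cKO, and Igf2 27 and 12, with exact permutation p-values of 0.886 and 0.114. Foxf1, Foxf2, Foxl1 and Foxe1 had at most 5 pooled counts in either group, and differences in them were not detectable at this depth.

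For 4 genes recalled from the published work on these mice as Hedgehog-dependent in cortical astrocytes, the fold changes were all positive. This list may have been chosen on these samples, so neither the direction nor a pass over the list alone is independent evidence. Sparc passed over all genes and all 4 passed when adjusted over the list alone. Lrig1, a leucine-rich repeat membrane protein, had 14.1 ± 2.72 CPM in WT and 31.3 ± 10.4 CPM in Ptch1cKO (SD, n = 4), with a log2 fold change of 1.16 (SE 0.26; edgeR, Benjamini-Hochberg adjusted p = 0.126) and no overlap between groups. An exon of Lrig1 overlaps opposite-strand Slc25a26. DESeq2 called Lrig1 (Benjamini-Hochberg adjusted p = 0.00666). In the 6 libraries with under 10 Xist counts, which are fewer samples, Lrig1 had a log2 fold change of 1.08 (SE 0.32) and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.423). The synapse-promoting Sparc relative Sparcl1 had a log2 fold change of 0.67 (SE 0.24) and the inwardly rectifying potassium channel Kcnj10 one of 0.52 (SE 0.18), with edgeR Benjamini-Hochberg adjusted p-values of 0.42 and 0.404. Of 23 tested astrocyte-secreted or surface regulators of synapses, Sparc alone passed over all genes. Adjusted over the list alone, Sparc and Lrig1 were higher and Ephb1 was lower.

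Of 34 gene lists tested, 7 passed camera with its preset correlation of 0.01, 6 with higher and 1 with lower values in Ptch1cKO. None held with an estimated correlation, where each had an adjusted p = 0.794 with an estimated correlation (Benjamini-Hochberg). No member of these 7 lists passed over all genes by edgeR, so their members are given as values only. Mature astrocyte markers had positive fold changes in 16 of 20 tested genes (camera, Benjamini-Hochberg adjusted p = 0.0074; p = 0.294 with an estimated correlation). The largest was for Itih3, with 29.1 ± 11.6 CPM in WT and 128 ± 70.4 CPM in Ptch1cKO (SD, n = 4), the one member that passed adjusted over the list alone. Ntsr2, a neurotensin receptor, had a log2 fold change of 0.56 (SE 0.18), and the connexin Gjb6 had 0.80 (SE 0.29). Aldh1l1, a widely used marker of the cell type, had 127 ± 30.9 CPM in WT and 134 ± 27.3 CPM in Ptch1cKO (SD, n = 4). In the glutamate uptake and potassium buffering list, 14 of 19 genes were positive (camera, Benjamini-Hochberg adjusted p = 0.0385; p = 0.393 with an estimated correlation). Adjusted over the list alone, 1 was higher and 1 lower. These were the potassium channel Kcnj16 at 1.07 (SE 0.23) and the metabotropic glutamate receptor Grm3 at -0.70 (SE 0.20). The astrocyte marker list did not pass camera without WT replicate 2 or Ptch1cKO replicate 2 (Benjamini-Hochberg adjusted p = 0.216 and 0.163). The glutamate and potassium list did not pass without WT replicate 1, WT replicate 2, Ptch1cKO replicate 2 or Ptch1cKO replicate 4 (camera, Benjamini-Hochberg adjusted p = 0.117, 0.348, 0.422 and 0.122).

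Genes of energy metabolism had positive fold changes in most members. In the glycolysis and lactate list 18 of 21 genes were positive (camera, Benjamini-Hochberg adjusted p = 0.000683; p = 0.102 with an estimated correlation), and 2 were higher when adjusted over the list alone. Gapdh had 1139 ± 171 CPM in WT and 1680 ± 93.4 CPM in Ptch1cKO (SD, n = 4), Gpi1 a log2 fold change of 0.40 (SE 0.11) and Ldhb one of 0.51 (SE 0.17). Exons of Gapdh and Gpi1 overlap genes on the opposite strand. Of 31 nuclear-encoded respiratory chain subunits, 26 were positive (camera, Benjamini-Hochberg adjusted p = 0.0385; p = 0.43 with an estimated correlation), 0 passed by edgeR when adjusted over the list alone, and 0 had an unadjusted p under 0.05. Cox6c, Cox6a1 and Atp5c1, the members with the smallest p, had log2 fold changes of 0.35, 0.29 and 0.23. The respiratory chain list did not pass camera without WT replicate 1, WT replicate 2, Ptch1cKO replicate 2 or Ptch1cKO replicate 3 (Benjamini-Hochberg adjusted p = 0.0966, 0.258, 0.521 and 0.123), nor in the 6 libraries with under 10 Xist counts (Benjamini-Hochberg adjusted p = 0.194).

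Microglial and interferon-stimulated genes had higher levels in the mutant libraries on average. Among microglial markers 15 of 16 were positive (camera, Benjamini-Hochberg adjusted p = 0.000683; p = 0.213 with an estimated correlation). Ptprc, the leukocyte antigen CD45, was the one member higher when adjusted over the list alone, at 10.2 ± 2.94 CPM in WT and 20.1 ± 5.60 CPM in Ptch1cKO (SD, n = 4). Siglech had a log2 fold change of 0.80 (SE 0.26) and the complement gene C1qc one of 0.99 (SE 0.37). The mean log2 CPM of the microglial markers, 4.32 ± 0.44 in WT and 4.80 ± 0.55 in Ptch1cKO (SD, n = 4), did not pass as a difference between libraries (exact permutation test, p = 0.229; Benjamini-Hochberg adjusted p = 0.533 over 14 library values). Without WT replicate 3, the library with the lowest microglial level at 3.68, the list did not pass camera (Benjamini-Hochberg adjusted p = 0.0869). Of 8 tested interferon-stimulated genes 7 were positive (camera, Benjamini-Hochberg adjusted p = 0.0121; p = 0.129 with an estimated correlation) and none passed by edgeR adjusted over the list alone. Oasl2, Ifi27 and Ifit3 had log2 fold changes of 1.58 (SE 0.57), 0.87 (SE 0.33) and 1.01 (SE 0.41), and unadjusted p-values under 0.05 were found for 3 of the 8. The interferon list did not pass camera without WT replicate 3 or in the 6 libraries with under 10 Xist counts (Benjamini-Hochberg adjusted p = 0.0635 and 0.0554).

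Neural stem and progenitor genes were lower on average. In this list 9 of 14 genes were negative (camera, Benjamini-Hochberg adjusted p = 0.0414; p = 0.191 with an estimated correlation), and by edgeR 0 passed adjusted over the list alone, with 4 having an unadjusted p under 0.05. The transcription factor Pax6 had 85.8 ± 26.3 CPM in WT and 50.5 ± 11.4 CPM in Ptch1cKO (SD, n = 4). Dlx1, a transcription factor of the interneuron lineage whose exons overlap opposite-strand Dlx1as, had a log2 fold change of -1.87 (SE 0.62), which rested on WT replicate 1, with 20.5 CPM, and was -0.74 (SE 0.47) without that library. The Notch target Hes1, going the other way, had 1.34 (SE 0.47). The list did not pass camera without WT replicate 1, WT replicate 2, Ptch1cKO replicate 2 or Ptch1cKO replicate 3 (Benjamini-Hochberg adjusted p = 0.181, 0.128, 0.247 and 0.0937), nor in the 6 libraries with under 10 Xist counts (Benjamini-Hochberg adjusted p = 0.0554).

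Markers of neurons, oligodendrocytes, oligodendrocyte precursors and endothelial cells did not pass camera, although the oligodendrocyte and precursor lists passed as higher without the filter on low counts (Benjamini-Hochberg adjusted p = 0.0302 and 0.0292), without WT replicate 2 (0.0185 and 0.0348) and without Ptch1cKO replicate 1 (0.0432 and 0.0499). The precursor list also passed in the 6 libraries with under 10 Xist counts (camera, Benjamini-Hochberg adjusted p = 0.00852). The Benjamini-Hochberg adjusted p-values of the 27 lists that did not pass ranged from 0.106 to 0.959. Proliferation genes, with 11 of 12 tested members negative, did not pass (camera, Benjamini-Hochberg adjusted p = 0.113; p = 0.37 with an estimated correlation). They passed as lower without the filter on low counts (0.0242), in the 6 libraries with under 10 Xist counts (0.00852), and without WT replicate 3, WT replicate 4 or Ptch1cKO replicate 4 (camera, Benjamini-Hochberg adjusted p = 0.00488, 0.00404 and 0.0414). Without WT replicate 1 the adjusted p was 0.819 (camera, Benjamini-Hochberg). The lists of synapse regulators, lipid transport, Wnt targets, Notch targets and gap junction proteins each passed as higher without WT replicate 3 and without Ptch1cKO replicate 3. Of 14 values taken per library, covering total counts, genes detected, the share of the 20 most abundant genes and the levels of 11 cell type lists, 0 differed between groups after Benjamini-Hochberg adjustment (exact two-sided permutation tests). The smallest p was for the share of the 20 most abundant genes, 19.5 ± 0.669% in WT and 20.9 ± 0.77% in Ptch1cKO (SD, n = 4), at p = 0.0286, the smallest that an exact test of 4 against 4 can give. A single value at that p has a Benjamini-Hochberg adjusted p = 0.4 over the 14 values, so this design could hardly call any of them.

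**Figure D2:**
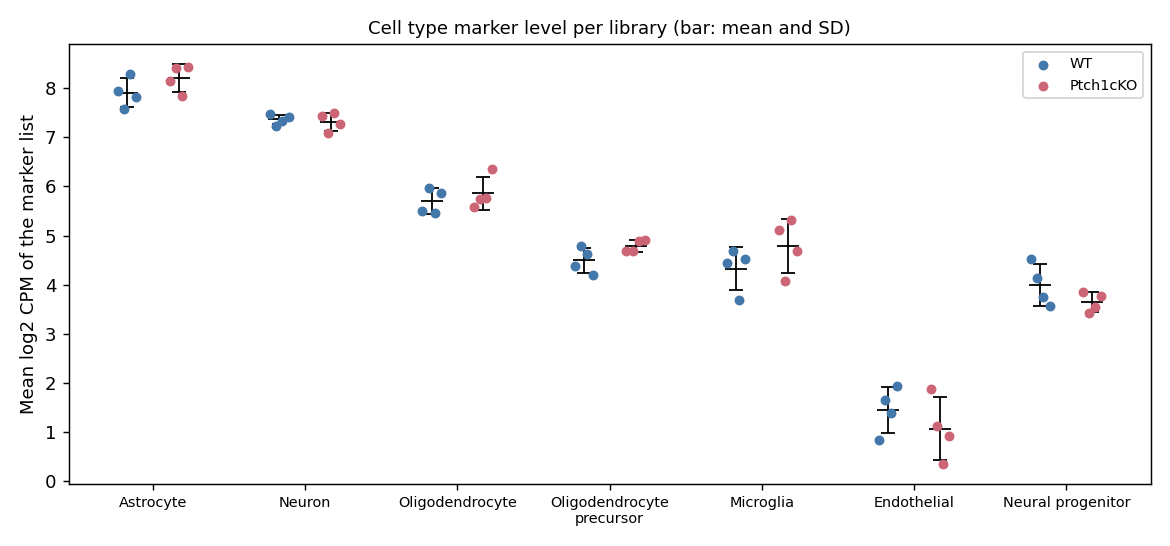
Mean log2 CPM of 7 cell type marker lists (vertical axis) in each WT and Ptch1cKO library; points are libraries, and bars are the mean and SD. The microglial level was 4.32 ± 0.44 in WT and 4.80 ± 0.55 in Ptch1cKO, and the ranges of the groups overlap.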

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

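The tests of sex, of microglial RNA and of astrocyte RNA in this part were chosen only after the results were seen; the counts over other splits of the samples were planned.

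Single libraries stood far from the rest of their group in 2 of 114 values examined, where chance gives about 5.7. Dlx1 had 20.5 CPM in WT replicate 1 against 2.66 to 5.03 CPM in the other WT libraries. Gapdh had 1541 CPM in Ptch1cKO replicate 2 against 1711 to 1737 CPM in the other Ptch1cKO libraries.

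The first pattern is the set of 11 genes that differed, led by Sparc. For their number, 1 of the 35 splits of the 8 libraries, the real one, gave 11 genes and the highest of the others gave 2. That is the lowest share that 35 splits can give, so it argues against chance but does not exclude it. For Sparc, male-pattern libraries alone gave a log2 fold change of 1.35 (SE 0.20), and the microglial and astrocyte marker levels as covariates gave 1.58 (SE 0.15) and 1.33 (SE 0.16), which argues against sex, microglial RNA or more astrocyte RNA per library as the whole cause. For the other 10 genes the median change, signed by the call, was 1.28 in male-pattern libraries (SE 0.30, taken over genes) and 1.31 in all 8. These genes were chosen and signed on all 8 libraries, which include the 6 of male pattern. The median was therefore likely to stay high, and it cannot decide whether sex plays a part. None of the 10 passed in the 6 libraries. A biological effect of the Ptch1 deletion on Sparc is a hypothesis; whether collection or library preparation differed between genotypes is not given and stays open.

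The second pattern is the set of 7 gene lists that passed camera. Chance could not be excluded for their number, since 18 of the 35 splits gave at least 7 lists and the highest of the others gave 19. In the microglial list 93.75% of the 16 tested members shared the positive sign. This had been seen before it was tested and decides nothing about microglial RNA carried through the tdTomato sort, which stays open; Csf1r, an abundant member, had 173 CPM in WT and 205 CPM in Ptch1cKO. A change of microglia with genotype stays open and was not tested.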

How the results depend on the processing

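Sparc was called in 25 of 25 alternatives (log2 fold change 1.33 to 1.61), including each library left out. The other called genes kept their direction in all 25 but were called in 9 to 16 of them. The number of genes that differed was 11 with RLE and upper-quartile scaling, without Rn45s and with a fold change of at least 1.5, 10 with limma-voom, and 9 with at least 1 CPM in at least 4 libraries, which kept more genes than the main filter. It was 83 with DESeq2, 21 with voom sample weights, 199 without a count filter, 2 on log2 TPM with either pseudocount, 2 with Xist as a covariate, 4 with 1 surrogate variable and 1 with the endothelial level as a covariate. Among alternatives added after seeing the data, it was 3 in the 6 libraries with under 10 Xist counts, 23 with the astrocyte and 69 with the microglial level as a covariate. The first of these has fewer samples; the cause was otherwise not tested. Chance could not be excluded for the 199 genes, since 2 of the 35 splits gave as many and the other of these gave 244, parting WT replicates 1 and 2 and Ptch1cKO replicates 1 and 3 from the rest. Leaving out WT replicates 1 to 4 gave 2, 1, 1 and 1 genes and leaving out Ptch1cKO replicates 1 to 4 gave 6, 19, 4 and 2.

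Ptch1 stayed lower in all alternatives, from -0.48 to -0.84 with a library left out and at its smallest, -0.38 (SE 0.20), with the microglial level as a covariate. It passed without a count filter at -0.66 and with the astrocyte level as a covariate at -1.01 (edgeR, Benjamini-Hochberg adjusted p = 0.00235 and 0.0189, against up to 0.696 in other alternatives); the cause was not tested. Nkx2-2 reversed to -0.031 with the astrocyte level as a covariate; the cause was not tested.

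The number of gene lists was 7 with RLE scaling, 0 with an estimated correlation, 0 with fry, 17 without a count filter, Hedgehog targets among them, and 7 in the 6 libraries with under 10 Xist counts, 4 of them shared. Leaving out a library gave 4 (WT replicate 1 or Ptch1cKO replicate 2) to 11 (WT replicate 3 or Ptch1cKO replicate 3).

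With the replicate number as a block, 5 genes (4 shared with the 11) and 10 lists were called, the precursor, reactive and cell cycle lists in addition to the 7, and Ptch1 was at -0.62. The values gave no sign that the numbers pair the samples. Same-number correlations ran from -0.17 to 0.018 over 4 pairs, and 0 WT libraries correlated best with their own number. Only the numbers of the titles were examined, and 4 pairs cannot exclude a pairing.

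Of 1.5-fold changes 14% were recovered in simulated data, so smaller changes are largely out of reach at this depth and number of libraries.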

Other observations

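The tests of the Bergmann glia and lysosomal lists were chosen after the gene results were seen, and neither list was among the 41 written before. The genes named in this part were also chosen after their values were seen.

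Several genes of axon guidance and cell adhesion had lower levels in Ptch1cKO without passing over all genes. Celsr3, an atypical cadherin, had 21.9 ± 7.63 CPM in WT and 6.57 ± 3.04 CPM in Ptch1cKO (SD, n = 4), and the netrin receptor Dcc 82.6 ± 24.4 and 40.0 ± 10.2 CPM. The repellent ligand Slit2 had a log2 fold change of -1.35 (SE 0.30), the teneurin Tenm3 -0.66 (SE 0.13) and the ephrin receptor Epha4 -0.82 (SE 0.20), with edgeR Benjamini-Hochberg adjusted p-values of 0.0772 for Celsr3, 0.109 for Dcc, 0.125 for Slit2, 0.0782 for Tenm3 and 0.173 for Epha4. In the list of adhesion and guidance proteins, 23 of 36 genes were negative (camera, Benjamini-Hochberg adjusted p = 0.164), and adjusted over the list alone Dcc, Slit2 and Epha4 were lower and Flrt1 was higher. The reactive astrocyte list did not pass camera (Benjamini-Hochberg adjusted p = 0.106, passing without the filter on low counts at 0.0242 and without WT replicate 2, Ptch1cKO replicate 2 or Ptch1cKO replicate 4 at 0.0321, 0.00157 and 0.0297); Serpina3n had 4.69 ± 3.23 CPM in WT and 19.5 ± 8.35 CPM in Ptch1cKO (SD, n = 4), whereas Gfap had 205 ± 144 and 217 ± 161 CPM.

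Transcripts of other cell types were abundant in both groups. Kif5a, a neuronal kinesin, had 21838 ± 1893 CPM in WT and 27809 ± 3907 CPM in Ptch1cKO (SD, n = 4). Camk2a had 9389 ± 530 and 9304 ± 936 CPM, the myelin gene Mbp 13613 ± 3625 and 14757 ± 1806 CPM, and Snap25 3682 ± 550 and 3333 ± 431 CPM. For the astrocyte glutamate transporter Slc1a2 the values were 18620 ± 3929 and 15926 ± 6329 CPM. These counts do not show which cells a transcript came from. The changes of the called genes, Gria1 and Kcnip3 included, therefore cannot be assigned to astrocytes alone.

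Ctsa and Ctsd, which encode lysosomal proteases, were among the genes with the smallest unadjusted p, with log2 fold changes of 0.73 (SE 0.15) and 0.79 (SE 0.18; edgeR, Benjamini-Hochberg adjusted p = 0.103 and 0.126). A list of lysosomal genes without these was therefore tested for the hypothesis that such genes are raised together. It had 16 of 21 positive members and a median log2 fold change of 0.24 (camera p = 0.00666 with an estimated correlation, Benjamini-Hochberg adjusted p = 0.0133 over both added lists), led by Ctsb at 0.56 (SE 0.13) and Hexa at 0.77 (SE 0.28), none of which passed over all genes. So small a p was found in 1 of the 35 splits, the real one, and the smallest of the others was 0.0704. The list was picked from Ctsa and Ctsd in the real split, so neither this count nor the p adjusted over both added lists excludes chance. With the microglial level as a covariate the median log2 fold change of the list was 0.26 (camera p = 0.0239 with an estimated correlation). The rise was not lost with this covariate, but its p rests on the same choice of list and does not settle the microglial share. A rise of lysosomal genes in the mutant libraries may be a candidate for follow-up and remains a hypothesis, and the cells it came from are not known.

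Gria1 is characteristic of Bergmann glia, the cerebellar astrocytes in which Hedgehog signalling is strong. A list of Bergmann glia genes without Gria1 was tested for the hypothesis that these genes rose with it. Of 6 tested members 3 were positive, and the median log2 fold change was -0.05. The list did not pass limma camera (Benjamini-Hochberg adjusted p = 0.148 over both added lists, equal to the unadjusted value). Gria4, another AMPA receptor subunit of Bergmann glia, had a log2 fold change of -0.52 (SE 0.21).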
